A study of Rattus norvegicus with 6 samples.

How the data were processed

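RNA from fetal rat penile tissue was sequenced in pairs of reads on an Illumina NovaSeq instrument, per the labels' protocols, in 3 control and 3 case libraries. HISAT2, featureCounts and the genome build Rnor_6.0 are named in the submitters' processing notes, without version, role or settings. Strandedness, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Paralogs, overlapping genes and antisense genes can therefore share reads in ways that could not be checked. The deposited table holds estimated counts per Ensembl gene, one column per library, with 378 values that are not whole among 23091 genes and 6 libraries. The labels mention no adjustment of these counts after counting. The values themselves show a relation between the libraries numbered 3 and the other 4 that independent libraries do not have, so they are not read here as raw counts of independent libraries. The test over 6 libraries assumes independence, and its results are given with those of the libraries numbered 1 and 2 alone and of a fit with number 3 as a batch term. Neither alternative undoes that relation.

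Values were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with its default minimum count of 10 and minimum total of 15, and libraries were scaled by TMM. The comparison of case with control used edgeR's quasi-likelihood test (glmQLFit with robust estimation and glmQLFTest, two-sided, group as the single term), with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes, and shares are percentages of all counts. Ratios of genes with few counts use summed counts scaled by library size, with exact binomial (Clopper-Pearson) intervals at 95%. Such intervals cover counting error at most, as no molecular identifiers are named. They assume raw counts of independent libraries, which these values are not taken to be. A count of 0 was read against a floor of 3 counts, which is 0.170 to 0.241 CPM per library without TMM scaling.

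Pairs of libraries of one group differed by 5.19 to 8.27 times the sampling noise (chi-square per degree of freedom over genes with a summed count of at least 20), so none was treated as a repeat of another. Pearson correlations of log2 CPM (prior count 2) across genes were 0.981 to 0.989 within groups and 0.980 to 0.986 between groups, over genes that are not independent replicates. Principal components were computed on the same log2 CPM. Over all tested genes, component 1 (29.3% of the variance) set both libraries numbered 3 apart from the other 4, and component 2 (24.7%) separated cases from controls. Without the 57 genes that were at 0 in both libraries numbered 3, component 1 (31.5% of the variance) separated cases from controls. Component 2 (25.4%) set controls 1 and 2 and case 3 apart from control 3 and cases 1 and 2.

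The rule for named genes, fixed before the data were examined, took the 12 largest changes per direction among genes that passed the test, had a mean log2 CPM of at least 1, showed no overlap between groups and had a symbol. The reference gene table given (assembly GRCr8) matched 0 of the 23091 identifiers, so the symbol clause was dropped and the 2 largest per direction are given by identifier. For the same reason the 46 gene lists fixed beforehand, their set tests, the genes always to be named and the check of sex chromosome genes were not analysed here. The alternative that leaves blood, muscle and mitochondrial genes out of the scaling was not run either.

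The test was checked on simulated counts drawn from the means and library sizes of the case against control comparison, with 200 genes changed. Over 14159 genes it recovered 70.1% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 92.4% of those changed 4-fold, and 14 of 182 calls (7.69%) were false. These simulated libraries were independent of each other.

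Other settings chosen before the data were examined were RLE scaling, library size alone, no low-count filter, a mean count of at least 10, DESeq2, limma-voom with and without quality weights, a replicate block, 1 surrogate variable from sva, and each library left out. Added after seeing the data were the libraries numbered 1 and 2 alone, number 3 as a batch term, the 57 genes left out, an interaction of group with number 3, and a comparison with simulated libraries adjusted by ComBat-seq (in sva) with and without the group, at the estimated dispersion and at 3 times that dispersion. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1 and sva 3.50.0 were used.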

Results

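RNA was sequenced from the penile tissue of rat fetuses, with 3 libraries labelled control and 3 labelled case. Per the series description, pregnant Sprague-Dawley rats, an outbred laboratory stock, were dosed by gavage on gestational days 12 to 19. They received di-(2-ethylhexyl) phthalate (DEHP), a plasticizer with anti-androgenic activity in male rat fetuses, or corn oil. Tissue was then taken at caesarean section from male fetuses with hypospadias, a urethral opening displaced along the underside of the penis, and from normal male fetuses. The labels do not say which of exposure and phenotype defines a case, and the 2 cannot be separated in this design. Nothing in the labels says that the 3 libraries of a group came from separate fetuses, litters or dams, so p-values measure the spread between these libraries, which may be technical. The libraries held 12435824, 12654750 and 17642369 counts in controls 1 to 3 and 14304926, 14824182 and 15860435 in cases 1 to 3. Between 16101 and 16439 of the 23091 listed genes had a count in a library. Genes are listed by Ensembl identifier, and none was matched to a symbol, so pathways and cell types were not analysed here.

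The comparison of case with control libraries asked which transcripts differed between the penile tissue labelled case and that labelled control. The most abundant gene that rose took 0.974% ± 0.0395 of all counts in controls and 1.59% ± 0.0764 in cases (SD, n = 3 each), a log2 fold change of 0.73 (SE 0.08; edgeR quasi-likelihood test, adjusted p = 0.00786). The next most abundant gene that rose went from 0.938% ± 0.0665 to 1.505% ± 0.145 of counts (SD, n = 3 each), a log2 fold change of 0.70 (SE 0.10; edgeR, adjusted p = 0.0208). Both were singled out after their values were seen. Together, the 187 genes that rose held 2.85% ± 0.105 of counts in controls and 4.43% ± 0.219 in cases. The most abundant and the next most abundant gene made up most of each of these shares. The 183 genes that fell held 1.60% ± 0.0246 in controls and 1.24% ± 0.0290 in cases (SD, n = 3 each). These shares were computed on the genes that passed the test, so their separation follows from that choice.

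Among identifiers taken by the rule for named genes, ENSRNOG00000017586 had the largest rise. It had 1, 1 and 0 counts in controls 1 to 3 and 65, 42 and 55 in cases 1 to 3. The scaled case-to-control ratio was 78.0, with a 95% exact counting interval of 21.2 to 649 (edgeR, adjusted p = 0.00346). Its fitted log2 fold change moved from 6.04 to 5.37 without control 3. ENSRNOG00000061320 had 0, 0 and 8 counts in controls and 74, 137 and 89 in cases, a ratio of 36.1 with an interval of 18.1 to 84.4 (edgeR, adjusted p = 0.0143). Its call was lost without control 1 (log2 fold change 4.65; edgeR, adjusted p = 0.0571) and without control 2 (log2 fold change 4.67; edgeR, adjusted p = 0.0502), against 5.14 over the 6 libraries. The fitted value became 9.56 without control 3 and 9.63 in the libraries numbered 1 and 2 alone, where all remaining controls were at 0, so that these fits depend on the prior count and give no size. The intervals of both ratios assume raw counts and leave out the spread between libraries.

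ENSRNOG00000019321 fell from 5.80 ± 0.982 CPM in controls to 1.14 ± 0.0542 CPM in cases (SD, n = 3 each). Its log2 fold change was -2.34 (SE 0.19; edgeR, adjusted p = 0.00346). ENSRNOG00000028436 fell from 6.95 ± 1.58 CPM to 1.49 ± 0.288 CPM (SD, n = 3 each), a log2 fold change of -2.23 (SE 0.23; edgeR, adjusted p = 0.00814). The 4 genes had between 0 and 137 counts per library, so their folds rest on few reads.

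**Figure D1:**
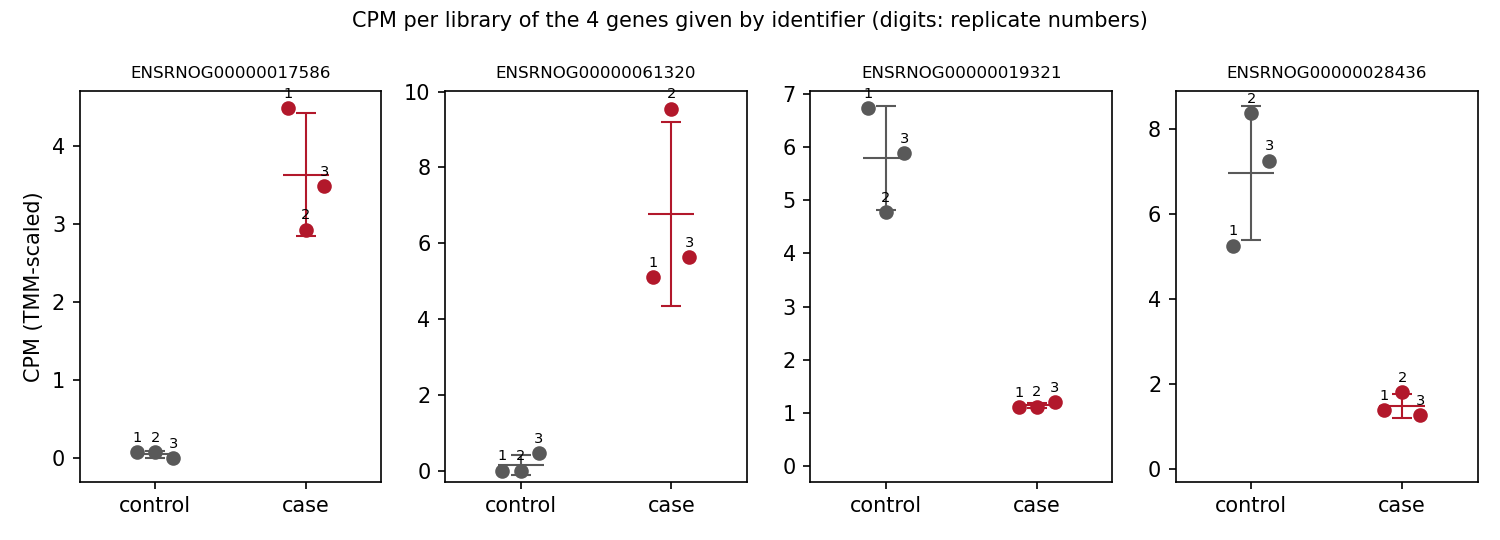
CPM values, scaled by TMM factors, of the 4 genes given by identifier in 3 control (grey) and 3 case (red) libraries. Points are libraries with their replicate numbers, and bars show the mean and SD. ENSRNOG00000019321 stood at 5.80 ± 0.982 CPM in controls and 1.14 ± 0.0542 CPM in cases.

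Of 14322 genes tested, 370 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 187 higher and 183 lower in cases. The balance moved with the scaling, to 206 higher and 147 lower with RLE factors and to 171 higher and 241 lower with library size alone. The median change was 1.44-fold among genes that rose and 1.33-fold among genes that fell, and 54 genes changed at least 2-fold, 23 of them upward and 31 downward. At an unadjusted p under 0.05 there were 2315 genes, where chance would give about 716 if the libraries were independent. They are not, so 716 is no fair measure of chance here. Splits of the 6 libraries into 3 and 3 other than the real one gave 13 to 1917 such genes (edgeR). Among called genes, changes of at least 2-fold lay mainly at low abundance. Few counts make smaller changes harder to call there, so this need not be a trait of the difference between groups. The share of tested genes called was 2.24% at 1 to 10 CPM and 2.92% at 100 to 1000 CPM. Of the 78 genes called at a mean of 1 to 10 CPM, 16 rose and 26 fell by at least 2-fold. Of the 222 called at 10 to 100 CPM, 3 rose and 3 fell by that much. Of the 62 called at 100 to 1000 CPM (26 higher, 36 lower), 2 rose and 0 fell by at least 2-fold. Above 1000 CPM, 3 genes were called higher and 1 lower, and 0 of them changed by that much.

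**Figure D2:**
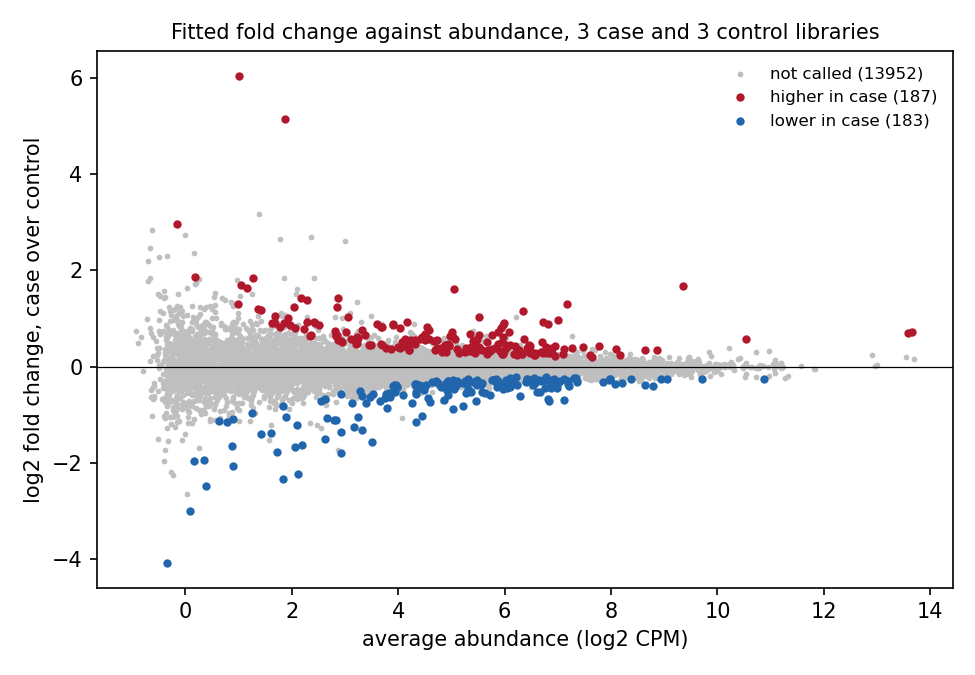
Log2 fold change of case over control (vertical) against average abundance in log2 CPM (horizontal) for the 14322 genes tested in 6 libraries. Red points are the 187 genes higher in cases, blue points the 183 lower, and grey points genes that did not pass the test. Larger fold changes lie at low abundance, where few counts make smaller changes harder to call.

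The 2 libraries numbered 3 stood in a fixed relation to the other 4. Over 10587 genes with at least 100 counts in every library, the mean of control 3 and case 3, on the CPM scale, differed from the mean of the other 4 by a median of 0.158%. The variance of that difference was 0.0179 of what counting alone gives. For the other 14 pairs of libraries the same ratio ran from 3.23 to 20.4. In addition, 57 genes had no count in either library numbered 3 and at least 5 counts in each other library, where no other pair had more than 2 such genes. Of these 57 genes, 49 were tested over the 6 libraries. None was called by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 in edgeR. They were chosen for a count of 0 in 1 library of each group. The spread within groups is then so wide that they could hardly be called, so this decides nothing. In the libraries numbered 1 and 2 alone, 51 were tested, of which 1 was called higher and 6 lower in cases (edgeR). Over all genes, 243 of 14281 were called there. The test over 6 libraries treats them as independent, which these values are not, so its p-values carry that limit.

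**Figure D3:**
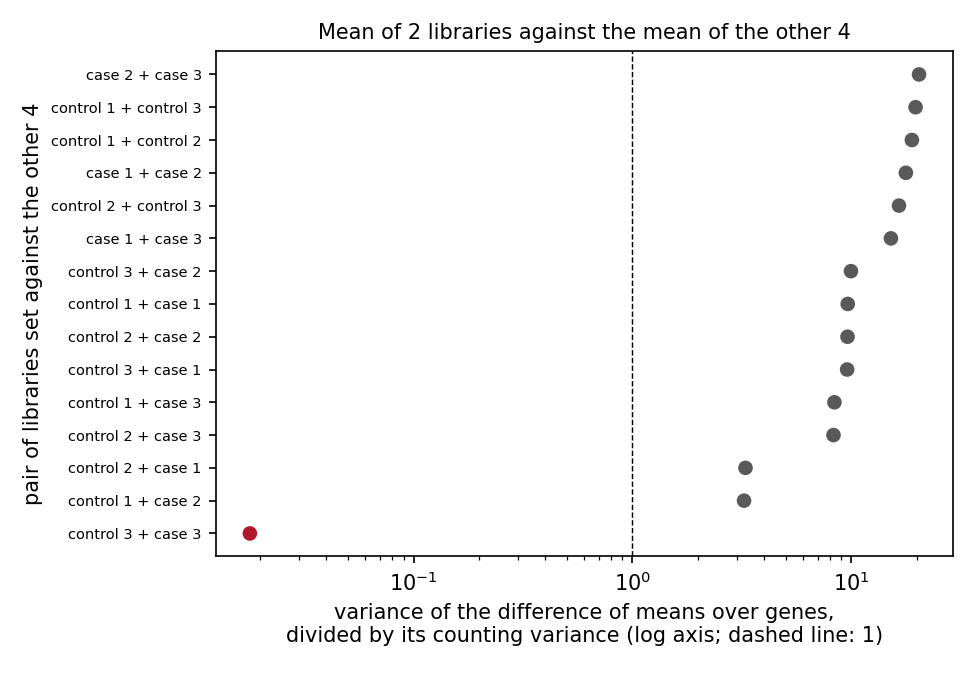
For each of the 15 pairs of libraries, the variance over 10587 genes of the difference between the mean of the pair and the mean of the other 4, divided by its counting variance (horizontal, log axis; the dashed line marks 1). The pair of libraries numbered 3 (red) lies at 0.0179 and the other 14 (grey) between 3.23 and 20.4.

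The comparison was repeated with this division treated separately, as alternatives chosen after seeing the data. If the values were adjusted between batches, the libraries numbered 1 and 2 would hold adjusted values too, so neither alternative is free of it. In the 4 libraries numbered 1 and 2, 243 genes passed the test, 125 higher and 118 lower in cases, and 154 of them were among the 370. The number 3 division holds 1 case and 1 control, which allows no test. Of the 243 genes, 236 had a count there. Of these, 166 (70.3%, exact 95% interval 64.1% to 76.1%) went the same way in case 3 against control 3, and 70 went the opposite way. The interval treats genes as independent, which they are not. All 154 genes also called over the 6 libraries went the same way, so the 70 lie outside the 370. That follows from the call over 6 libraries, which uses number 3, and is no separate evidence. With the division as a term in the edgeR fit over 6 libraries, 108 genes passed, 59 higher and 49 lower, 107 of them among the 370. Tied means left that term almost nothing to remove. Outside genes at or near 0 in number 3, it passed in 0 of 14249 genes. The median move of a log2 fold change for the group was -6.8e-06. Each group holds 1 library numbered 3, so this move would be near 0 whatever the term removed, and it decides nothing. Because the means are tied, the lower count is not read as a correction for the division. Leaving out any 1 library gave 61 to 132 calls.

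**Figure D4:**
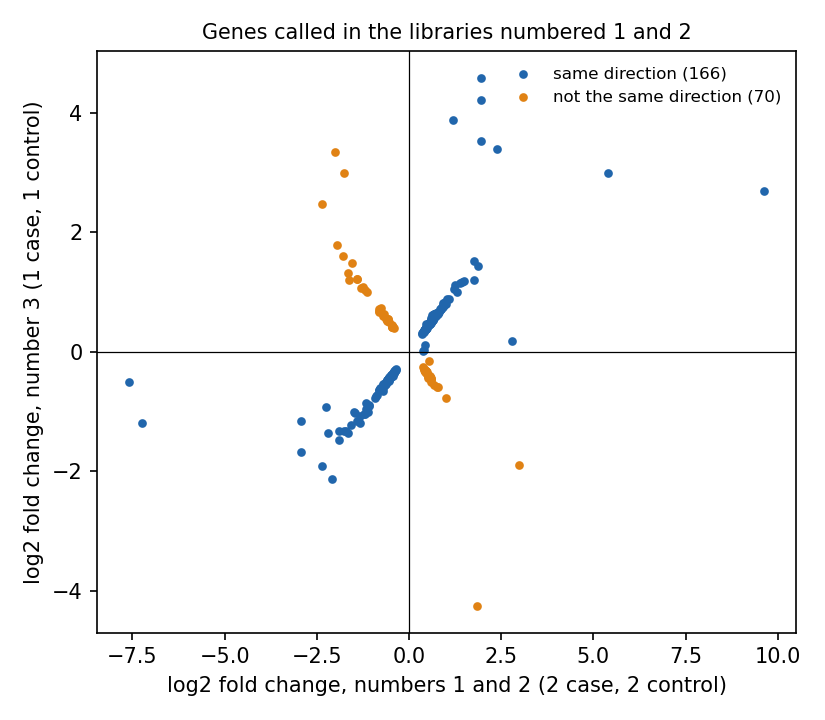
Log2 fold change in case 3 against control 3 (vertical, with 0.5 CPM added to each value) against the fitted log2 fold change in the libraries numbered 1 and 2 (horizontal) for 236 genes called in the latter. Blue points are the 166 genes with the same direction and orange points the 70 with the opposite direction. Most points lie along 2 lines of opposite slope.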

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

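The interaction described here was chosen after the data were seen, whereas the test of left-out pairs was written before its result was seen and its simulated values were added afterwards. In edgeR's quasi-likelihood fit with group, number 3 and their interaction, 126 of 14249 genes showed a case against control difference that differed between the libraries numbered 3 and those numbered 1 and 2. Genes with 3 or fewer counts over both libraries numbered 3 were left out. The interaction was positive for 80 genes and negative for 46, and 24 of the 126 also passed the test for group. Number 3 holds 1 library per group, so the spread comes from numbers 1 and 2 alone, with 2 residual degrees of freedom. The values of number 3 are also tied to the other 4 libraries, which makes this test unreliable, and the count is given as a description of these libraries only.

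Direction was compared separately, and whether the genes that turned are those of the interaction was not tested. Among the 236 genes called in the libraries numbered 1 and 2 and counted in number 3, the ratio of the fold change in number 3 to that in numbers 1 and 2 (on the log2 scale) had a median of 0.83 for the 166 that went the same way and -0.82 for the 70 that went the opposite way. A selection of chance extremes would send such genes each way about equally often. Over the 9 choices of a left-out control and case library, the lowest share with the same direction was 68.3%, for control 3 and case 3, counting 77 genes without the same direction, 7 of them at 0 in both libraries. This met the bound of 60% set beforehand, but that bound took the left-out pair as independent. In simulated unchanged groups adjusted between batches, the share was 45.9% and 46.9% without the group in the adjustment. It was 59.5% and 59.1% with the group, with exact 95% upper bounds of 68.5% and 67.4%. The observed 68.3% lay between these bounds. Over the 236 genes with a count in number 3 it was 70.3%, above both, with an exact 95% interval of 64.1% to 76.1% that reaches below both. Genes are not independent and simulated settings exclude nothing, so chance extremes stay open if the group was in the adjustment. The other 8 choices gave 97.2% to 100% on 2 to 94 calls. Their fits include libraries numbered 3, whose values are tied to the rest, so these shares are not independent evidence. None of the 70 was called over the 6 libraries, while all 154 genes called in both fits went the same way. Every call over the 6 libraries had its case and control libraries apart, so this contrast follows from the selection. What makes 70 genes turn is open. A difference between fetuses, litters or dams, or in severity, may add to it and was not tested. A near-constant size in both directions is also what an adjustment of spread between batches may leave, since in the deposited values the lower quartile of the half-difference between control 3 and case 3 was 0.51 SD of the other 4 libraries.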

How the results depend on the processing

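RLE scaling, library size alone, no filter, a mean count of at least 10, DESeq2 and limma-voom gave 338 to 415 calls, within 1.5 times the 370 reported. The share of calls higher in cases was 50.5% as reported, 58.4% with RLE and 41.5% with library size alone. In all 370 calls every case library lay on one side of every control library, so their direction could hardly change in any of these settings. Quality weights in limma-voom gave 3281 calls (1540 higher, 1741 lower, 208 at least 2-fold). They weighted control 3 by 3.22 and case 3 by 3.86 and no other library above 0.594, so the libraries that are tied to the rest counted most, and this number is not a gain in evidence. With 1 surrogate variable, 108 genes were called (59 higher, 49 lower, 30 at least 2-fold), and number 3 as a batch term gave the same 4 counts. The tied means leave a batch term little to remove, so neither count is read as a correction. The libraries numbered 1 and 2 alone gave 243 calls (118 lower). The batch term and the 4 libraries were chosen after seeing the data, as was leaving out the 57 genes (372 calls).

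Leaving out 1 library gave 61 to 132 calls (28 to 75 higher, 31 to 57 lower, 23 to 35 at least 2-fold): 61, 68 and 104 without controls 1 to 3, and 132, 117 and 107 without cases 1 to 3. Fewer libraries were then tested. Of the choices of 2 against 2 libraries, numbers 1 and 2 alone gave 243 calls and the others gave 2 to 94. Simulated unchanged groups adjusted without the group gave up to 82 calls in the libraries numbered 1 and 2. The 243 calls therefore cannot decide whether the number of libraries accounts for the fall. The cause was not tested further. Of 72 values for the 4 identifiers, 69 kept their call. ENSRNOG00000061320 lost it without control 1, without control 2 and with the replicate block (edgeR, adjusted p = 0.0736), with log2 fold changes of 4.65, 4.67 and 5.15 against 5.14.

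With the replicate block, 49 genes were called (32 higher, 17 lower, 12 at least 2-fold), 42 of them among the 370. Deviations of same-numbered libraries from their group means correlated at -0.03, 0.004 and -0.43. The tied means of number 3 distort these values, so the check decides nothing. The labels name nothing that same-numbered samples share, and the numbers were not used as pairs. Across genes of uncentred log2 CPM, controls 2 and 3 correlated best, among cases, with the case of their own number (0.986 and 0.982), and control 1 with case 2 (0.984). These genes include the 49 tested genes at 0 in both control 3 and case 3, which can raise the value of that pair. The planned set tests and the scaling without blood, muscle and mitochondrial genes were not run, as identifiers carried no names.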

Other observations

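The tests of the libraries numbered 3 in this part were chosen after the result was seen, and the count of other splits was planned. The mean of control 3 and case 3 lay within a median of 0.158% of the mean of the other 4 libraries. If 6 libraries had been sequenced independently, the difference of means would vary over genes by at least its counting variance. The observed ratio was 0.0179, which argues against independence. A candidate explanation is an adjustment of counts between 2 batches, number 3 and numbers 1 and 2. Unchanged groups with gene-wise batch shifts (SD 0.5 on the log2 scale) were simulated 5 times at the estimated dispersion and 5 times at 3 times that dispersion. They were then adjusted by ComBat-seq. Without the group in its model the ratio was 0.00452 to 0.00520 and 0.0151 to 0.0173, with the group 0.0132 to 0.0393 and 0.123 to 0.328, and unadjusted at least 220. The lower quartile of the half-difference between both libraries numbered 3, in SDs of the other 4, was 0.51 in the deposited values. It was 0.421 to 0.446 and 0.565 to 0.585 without the group, 0.191 to 0.202 and 0.164 to 0.177 with it. The observed upper quartile was 0.722, against 0.700 to 0.705 and 0.707 to 0.722 without the group and 0.728 to 0.771 and 0.644 to 0.670 with it. Without the group, the ranges at 3 times the dispersion held the upper quartile, the ratio lay just above them, and the lower quartile lay between the ranges at both dispersions. With the group, the ranges at the estimated dispersion held the ratio, and both ranges of the lower quartile lay far below the observed value. No setting matched every measure, the simulated settings exclude nothing, and whether the group was in the adjustment stays open. No label states such a step, and no biological explanation was tested.

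The 57 genes at 0 in both libraries numbered 3 bear on the same hypothesis. Sampling depth would need low expected counts, but the median gene would have had 47.6 counts over both libraries at the rate of the other 4. The most counted had 1043, 1184, 1026 and 894 counts in controls 1 and 2 and cases 1 and 2. An adjustment of counts between 2 batches may leave genes with no count in 1 batch as they were. That may account for the values above 1 that are not whole. All 282 of them lay in genes at 0 across number 3 or across the other 4. The best of the other 14 pairs placed 139. The 378 values that are not whole also include values under 1, which were not checked in this way. A test of a wider difference of RNA or library preparation in the libraries numbered 3 called 0 of 14249 genes outside the pattern in edgeR, and 0 at an unadjusted p under 0.05 where chance gives about 712. Tied means fix that outcome, so it decides nothing and such a difference before any adjustment stays open. How reads were assigned to genes had been considered first, because 12 of the 49 tested genes of the pattern and 2 of 14273 others had values that are not whole (one-sided Fisher's exact test, p = 5.4e-29). The same decimals are what the adjustment would leave, so they do not separate the 2 explanations.

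Whether the group was in the adjustment bears on the calls. In the simulated unchanged groups adjusted without the group, the test called 0 to 5 genes at the estimated dispersion and 0 to 2 at 3 times that dispersion, against 370 in the data. With the group it called 155 to 218 and 151 to 210. With a batch term these became 47 to 67 and 55 to 81, against 108 in the data. An adjustment with the group may therefore account for part of the 370 calls. The libraries numbered 1 and 2 alone gave 37 to 47 and 28 to 82 calls at the 2 dispersions in simulated groups adjusted without the group, and 14 to 28 and 13 to 44 with it, against 243 in the data. With no adjustment they gave 0 to 2 and 0 to 1. Testing these libraries alone therefore does not step outside an adjustment. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls as the real one, the real one itself. The highest other count was 81, for controls 1 and 2 with case 3 against the rest, which exchanges control 3 and case 3. That split had 1917 genes at an unadjusted p under 0.05 in edgeR, against 2315 in the real one. The remaining 8 splits gave 0 calls in edgeR. In 4 of these, control 3 and case 3 stand on the same side, the tied means hold the result near 0 (13 to 20 genes at an unadjusted p under 0.05, where chance gives about 716), and they are no fair comparison. In the other 4, 716 to 1789 genes had an unadjusted p under 0.05. With 10 splits the share cannot fall under 0.1.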
